A study of Homo sapiens with 65 samples.

How the data were processed

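The study measured RNA from whole blood of kidney transplant recipients at month 3 after transplantation on 65 arrays, with 1 array per sample. The sample titles number separate patients, so each array was taken as a separate recipient, and p-values measure the spread between these samples. The extraction and amplification kits are given in the labels, and RNA quality was assessed before labelling, without values used here. The deposited table held log2-scale values made with RMA in the Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalises quantiles across arrays and summarises the probes of each transcript cluster, which makes arrays alike in distribution and can hide a shift that all genes share. The log base was not stated, and values between 0.781 and 13.6 with array medians from 5.79 to 6.12 fit the log2 scale of RMA output. The same notes name the genome builds hg18 and NCBI36 without a role, and no coordinates are printed here. Versions of these tools, row filters, slides and scan dates are not given in the sources used here. Only the processed table was used, so another background correction or a slide as a block could not be run.

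The table held 16521 rows. A platform annotation table listed 13349 of them with 1 gene, 2215 with several genes and did not list 957. Entrez identifiers of 13329 rows matched the current gene table, which changed 0 symbols. The unlisted rows were left out of the test because they name no gene here, and 29 rows of XIST, TSIX or Y-linked genes were left out because donor sex is not reported. This left 15535 rows, of which those with several genes were tested and counted but never named. For gene lists, 1 row was kept for each of 13169 genes, the one with the highest mean among rows that name only that gene, and 171 genes had more than 1 row. Genes found only in rows with several genes were not measured in the lists. All 65 value columns were used, and 0 per-sample columns were left unused. No 2 arrays held the same values.

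ACR yes (12 arrays) was compared with ACR no (53 arrays) with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with the group as the only term, Benjamini-Hochberg adjustment over all rows tested and a threshold of 0.05. All tests are two-sided unless stated. The 30 gene lists cover blood cell types, responses and processes, as well as a published blood assay for rejection and a published common rejection module. A list score was the mean over its measured genes of z scores taken across the 65 arrays, and a list needed 5 measured genes. Group differences of scores were tested by permutation with 100000 resamples, adjusted over the lists. Intervals of 95% came from 10000 bootstrap resamples within groups, and intervals of ROC areas from DeLong's method in pROC 1.19.0.1. Beside this, camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry. Within each of the 2 ranges of title numbers, lists were tested by exact enumeration with numpy 2.4.6 and numba 0.67.0 in Python 3.11.15. The classifier was a diagonal linear discriminant on the 50 rows with the smallest p of each training part, in 4-fold cross-validation with 20 repeats, with 100 permuted labellings at 5 repeats each. Figures were drawn with matplotlib 3.10.9.

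The groups, tests, gene lists, rule for named genes and the settings listed below were fixed before the data were examined. The rule names the 12 genes with the smallest p in each direction, among rows that name 1 gene by a symbol other than a clone or predicted identifier and have a mean level at or above the 25th percentile of rows, and up to 4 members with the smallest p of a list. Genes named outside it are said to be chosen after their values were seen. Other settings tried were filters on dim rows, quantile normalisation or centring on top, other eBayes settings, array weights, the title number range as a block or within each range, blood composition scores as covariates, leaving out arrays over a quality limit, 1 row per gene, a threshold of 0.10, other list scores and tests, and 10 or 200 rows per classifier. The quality limit was the median plus 3 median absolute deviations of each array's interquartile range of relative log expression.

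The tests were run on simulated data first. Normal values were drawn for all 15535 rows in groups of 12 and 53, each row independently of the others, with 50 rows changed at each of several sizes. Limma recovered 24% of the rows changed by 0.25 on the log2 scale, 78% at 0.5, 94% at 1 and 100% at 2, and 6 of its 154 calls were false. The list test recovered the 1 shifted list alone, and the classifier gave an area of 0.481 with no changed row. Real rows vary together and some real arrays are outlying, so these rates need not hold for the real data.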

Results

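Gene expression was measured in the whole blood of kidney transplant recipients, sampled in month 3 after transplantation, with 1 exon-type oligonucleotide array per blood sample. The labels divided the 65 arrays into 12 with ACR yes and 53 with ACR no, where the series concerns subclinical acute rejection, that is, rejection found without a clinical sign. Array medians lay between 5.79 and 6.12 on the log2 scale, and the number of arrays limits the precision of every value. The median correlation between 2 arrays was 0.937, and the lowest was 0.298. 4 arrays spread over a quality limit of 0.554 for the interquartile range of relative log expression, against 0.347 on the median array. They were ACR_yes replicate 7 at 1.57, ACR_yes replicate 9 at 0.792, ACR_yes replicate 4 at 0.636 and ACR_no replicate 9 at 0.567, so that 3 of the 4 came from the smaller group (Fisher's exact test, two-sided p = 0.018).

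The comparison of ACR yes with ACR no asked which blood transcripts differ between recipients with and without this diagnosis. F13A1, the A chain of coagulation factor XIII, which platelets and monocytes carry, had the largest fall among the named genes. It fell by 1.23 on the log2 scale (SE 0.25), from 8.09 ± 0.71 (SD, n = 53) in ACR no to 6.86 ± 1.10 (SD, n = 12) in ACR yes, with a limma adjusted p of 0.00877. LGALSL, a galectin-related protein, fell by 1.11 (SE 0.23) and MSN, the cytoskeletal linker moesin, fell by 0.65 (SE 0.13). The smallest p belonged to TBL1X, a subunit of the NCoR and SMRT corepressor complexes, which fell by 0.60 (SE 0.10, limma adjusted p = 0.00205) and lay above the ACR no median on 0 of the 12 ACR yes arrays. In the other direction CHORDC1, a co-chaperone of HSP90, rose by 1.46 (SE 0.38, limma adjusted p = 0.0334) and lay above the ACR no median on 12 of 12 arrays. Limma pools the spread of both groups, and the SD was larger in ACR yes for the named genes other than CHORDC1, EXOSC3 and TRIAP1. MSN had an SD of 0.82 in ACR yes (n = 12) against 0.27 in ACR no (n = 53). Where the smaller group varies more, a pooled SE and its p can be too small, so such genes can look firmer than they are.

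The other named genes that fell act in signalling, the cytoskeleton, vesicle traffic and chromatin. The transcription factor STAT3 fell by 0.70 (SE 0.15), and INPP5D, the lipid phosphatase SHIP1 of blood cells, fell by 0.54 (SE 0.11). ARHGAP25 fell by 0.61 (SE 0.13) and SSH2, a phosphatase of the actin regulator cofilin, fell by 0.74 (SE 0.15). RAB11FIP1, an effector of the recycling GTPase Rab11, fell by 0.67 (SE 0.13), VAMP2, a SNARE protein of vesicles, by 0.46 (SE 0.10), and RNASEK, a small protein of the vacuolar proton pump, by 0.53 (SE 0.10). The histone acetyltransferase CREBBP decreased by 0.56 (SE 0.12). Limma adjusted p values of these 8 genes ran from 0.00233 for RNASEK to 0.0119 for CREBBP, INPP5D and VAMP2.

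Zinc-finger genes and genes of mitochondria, chromatin and RNA processing were among the named genes that rose. ZNF254 rose by 0.80 (SE 0.16, limma adjusted p = 0.00877), from 6.35 ± 0.48 (SD, n = 53) to 7.15 ± 0.66 (SD, n = 12). RBAK, a zinc-finger protein that binds the retinoblastoma protein, rose by 0.83 (SE 0.21) and ZNF510 by 0.54 (SE 0.14). COX7B, a subunit of cytochrome c oxidase, rose by 1.38 (SE 0.37), and MRPL48, a protein of the mitochondrial ribosome, rose by 0.46 (SE 0.12). EXOSC3, a subunit of the RNA exosome, was higher by 0.40 (SE 0.10), the histone methyltransferase SUV39H2 by 0.51 (SE 0.11), and the p53-regulated apoptosis inhibitor TRIAP1 by 0.58 (SE 0.15). GIN1 was higher by 0.65 (SE 0.16), CMAHP by 0.53 (SE 0.13) and ZNHIT3 by 0.52 (SE 0.12). Limma adjusted p values of these 11 genes ran from 0.00877 for ZNF254 to 0.0382 for ZNF510.

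Of 15535 rows tested, 235 passed an adjusted p of 0.05 in limma, 77 of them higher and 158 lower in ACR yes, so that 67.2% of the calls were lower. At an unadjusted p of 0.05 the number was 2392, where chance gives 777. The median absolute change of the called rows was 0.52 on the log2 scale, and 6 changed by over 1. Rows called higher were dim, with a median level of 4.72, and rows called lower were bright, with a median level of 7.94. With each array centred on its median the count stayed at 235, but 123 were then higher and 112 lower, or 47.7% lower.

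**Figure D1:**
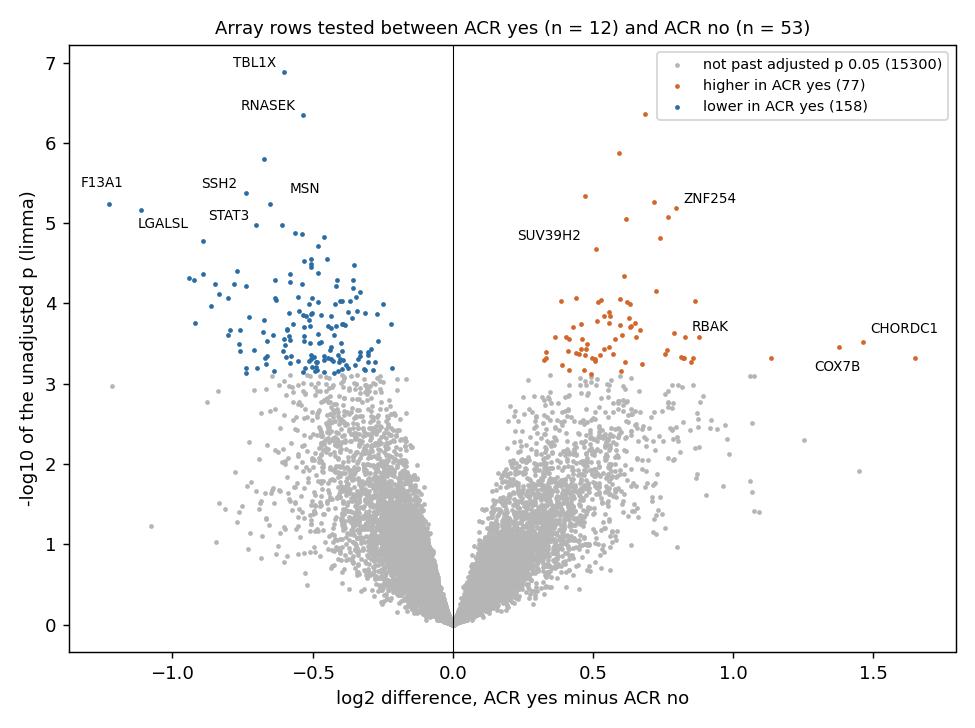
Each point is 1 of the 15535 rows, with the log2 difference of ACR yes (n = 12) minus ACR no (n = 53) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 77 orange and 158 blue points passed an adjusted p of 0.05, and F13A1 at -1.23 and CHORDC1 at 1.46 mark the named genes with the largest changes.

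The count rested on few arrays. Without the 4 arrays over the quality limit, limma called 4 rows, with 2888 at an unadjusted p of 0.05. These were TAGLN2, the actin-binding protein transgelin 2 (-0.95), the kinetochore gene NUF2 (0.61), the mitotic spindle gene HMMR (0.78) and TMEM53 (-0.25), named after their values were seen. All 235 rows kept their sign in that fit, and the 24 genes named above had limma adjusted p values from 0.0546 to 0.184. For 7 of the 24 the change shrank by over 1.5 times: F13A1 to -0.81, SSH2 to -0.47, STAT3 to -0.38, MSN to -0.30, CREBBP and INPP5D to -0.27, and ZNHIT3 to 0.29. Leaving out 1 array at a time moved the count by over 1.5 times for 11 arrays. It was 10 without ACR_yes replicate 9, 36 without replicate 4, 57 without replicate 5, 91 without replicate 11, 112 without replicate 6 and 144 without replicate 3. It was 2995 without ACR_yes replicate 7, 388 without replicate 12, 384 without replicate 8, 416 without ACR_no replicate 27 and 356 without ACR_no replicate 21. The labels number the recipients in 2 separate ranges, and within the lower range (4 ACR yes, 22 ACR no) 0 rows passed in limma, with 1291 at an unadjusted p of 0.05, and within the higher range (8 and 31) 3 rows passed. With the range as a block 275 passed. With Neutrophil, T cell, Erythroid and Platelet scores as covariates limma called 0 rows, with 1762 at an unadjusted p of 0.05. In that fit 15 of the 24 named genes moved by over 1.5 times, among them F13A1 to -0.35, CHORDC1 to 0.63 and COX7B to 0.66. F13A1 belongs to the Platelet list, so part of its shrinkage is built into that covariate. The Platelet score also differs between the groups, so this fit removes any group difference that goes with it and cannot decide its source.

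Transcripts carried by platelets were lower in ACR yes as a group. The Platelet list had a mean z score of -0.771 ± 0.513 (SD, n = 12) in ACR yes against 0.175 ± 0.692 (SD, n = 53) in ACR no, a difference of -0.945 (95% bootstrap interval -1.28 to -0.617). It was the 1 list of the 30 that passed (two-sided permutation p = 4e-05, adjusted p = 0.0012), but camera, which asks whether a list's genes move more than other genes, did not call it with an estimated correlation (adjusted p = 0.13), and 0 of 12 ACR yes arrays lay above the ACR no median. All 15 measured members had negative differences. In limma 7 fell over all rows tested, and 14 fell when adjusted over the list alone. F13A1 had the smallest p, followed by CLU, the secreted chaperone clusterin, which fell by 0.89 (SE 0.19), and by ITGB3, the beta-3 integrin of the fibrinogen receptor, which fell by 0.94 (SE 0.22). SPARC, a matrix protein of alpha granules, fell by 0.92 (SE 0.21). The member that did not pass either way was GNG11, a G-protein subunit, at -0.17 (SE 0.23). The area under the ROC curve of the list score was 0.137 (95% DeLong interval 0.0343 to 0.239), where 0.5 is no separation and values below it mean lower scores in ACR yes.

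The platelet difference held when any 1 array was left out, with adjusted p up to 0.006. Without the 4 arrays over the quality limit it was -0.919 (adjusted p = 0.0198). In the lower title number range it was -0.916 (exact permutation p = 0.0254, adjusted p = 0.261, 4 against 22), and in the higher range -0.976 (exact permutation p = 0.000548, adjusted p = 0.0164, 8 against 31). Without ACR_yes replicate 7 and with the first principal component of the other 64 arrays as a covariate, it was -0.485 (adjusted p = 0.114). Camera called the list with a preset correlation (adjusted p = 3.11e-13) but not with an estimated correlation. Fry, which tests whether a list's genes move on balance in 1 direction, gave an adjusted p of 0.00103.

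Cell division genes were higher by a list score that did not pass adjustment. The Cell cycle list differed by 0.497 (95% bootstrap interval 0.137 to 0.891, permutation p = 0.0103, adjusted p = 0.103), and 12 of 12 ACR yes arrays lay above the ACR no median. In limma 1 of its 17 measured members passed over all rows tested, and 3 passed when adjusted over the list alone. The mitotic kinesin KIF11 rose by 0.62 (SE 0.15, limma adjusted p = 0.0228). The spindle checkpoint kinase TTK differed by 0.22 (SE 0.07), topoisomerase TOP2A by 0.52 (SE 0.18) and the ribonucleotide reductase subunit RRM2 by 0.65 (SE 0.27). Camera with a preset correlation called this list, with an adjusted p of 0.43 with an estimated correlation. The score passed without ACR_yes replicate 7 (adjusted p = 0.0432) and without ACR_no replicate 39 (adjusted p = 0.0468). Without replicate 7 and with the component of the other 64 arrays as a covariate it was 0.59 (adjusted p = 0.114). With Neutrophil, T cell, Erythroid and Platelet scores as covariates it was 0.31 (permutation p = 0.114, adjusted p = 0.495).

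Mean scores of the gene lists from published rejection studies were not higher in ACR yes. A mean score counts every gene in the same direction and was taken in blood. It is thus not the published assay's own readout, nor a measure of the graft. The common rejection module, 11 genes described as raised in rejecting grafts, differed by -0.355 (95% bootstrap interval -0.646 to -0.0922, permutation p = 0.00656, adjusted p = 0.0984). Of its 10 measured members INPP5D passed over all rows tested in limma, and 4 were lower when adjusted over the list alone, among them the exonuclease ISG20 at -0.39 (SE 0.13), the granule protein NKG7 at -0.53 (SE 0.21) and BASP1 at -0.35 (SE 0.14). The score passed without ACR_yes replicate 7 (adjusted p = 0.0432), without ACR_yes replicate 5 (adjusted p = 0.0256) and without ACR_no replicate 39 (adjusted p = 0.0468). Without ACR_yes replicate 7 and with the component of the other 64 arrays as a covariate it was -0.293 (adjusted p = 0.169). With Neutrophil, T cell, Erythroid and Platelet scores as covariates it was -0.138 (adjusted p = 0.585), and without the arrays over the quality limit -0.271 (adjusted p = 0.306). Camera did not call it with a preset correlation (adjusted p = 0.125) or an estimated one (adjusted p = 0.784). The module passed without genes of the lower 50% by mean level, at -0.585 (adjusted p = 0.0029). That setting kept 8 members and left out CXCL9 (0.26, SE 0.13) and CXCL10 (0.39, SE 0.24), named after their values were seen. Both had positive differences, so this pass adds no weight to a fall of the whole module. The 17 genes of a published blood assay for rejection differed by -0.336 (permutation p = 0.0286, adjusted p = 0.163). This became -0.182 without the arrays over the quality limit (adjusted p = 0.662), -0.202 with the 4 composition scores as covariates (adjusted p = 0.495), and -0.0354 without ACR_yes replicate 7 and with the component (adjusted p = 0.921). Of its 15 measured members 0 passed in limma over all rows tested and 1 when adjusted over the list alone, the caspase-8 inhibitor CFLAR at -0.45 (SE 0.15).

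**Figure D2:**
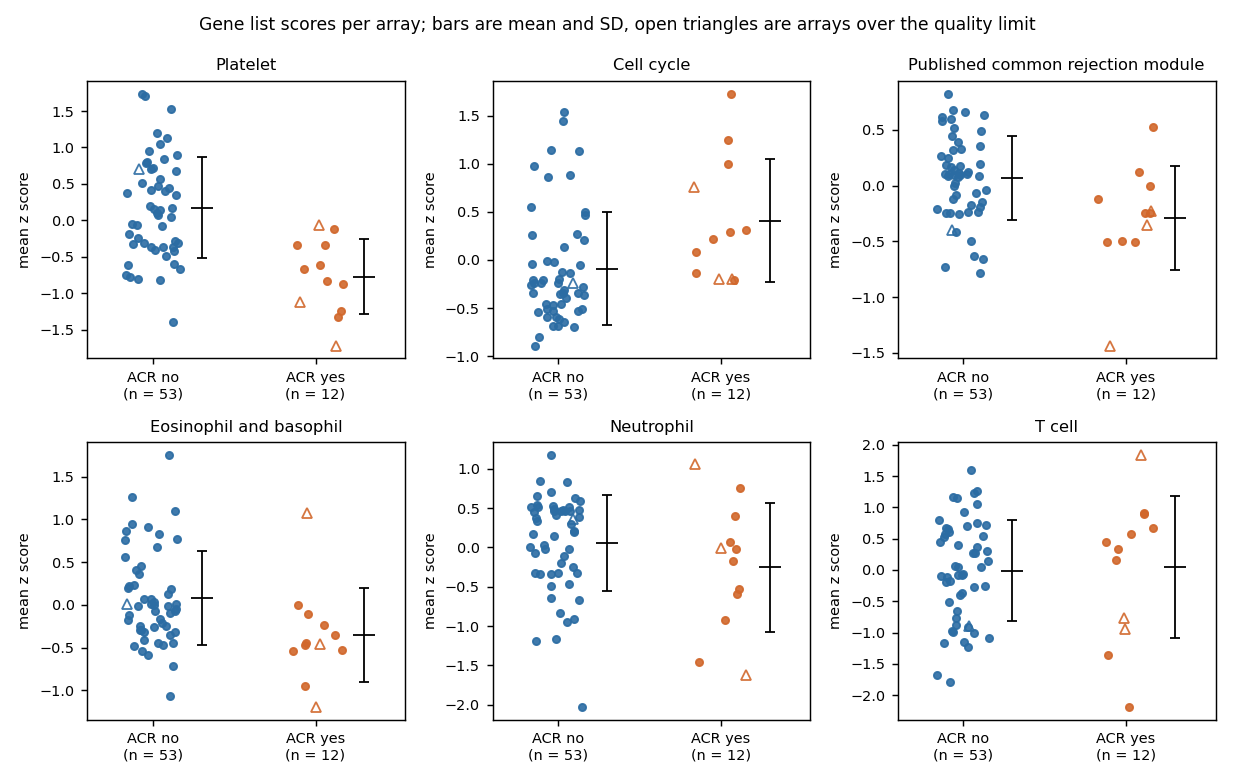
Mean z score per array for 6 gene lists, with each point 1 array, bars giving the mean and SD of ACR no (n = 53) and ACR yes (n = 12), and open triangles marking the 4 arrays over the quality limit. Platelet scores centre at -0.771 in ACR yes and 0.175 in ACR no, whereas the T cell scores of the groups overlap.

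Among myeloid and granulocyte lists, the Eosinophil and basophil list differed by -0.433 (permutation p = 0.0163, adjusted p = 0.122), led by the transcription factor GATA2 at -0.22 (SE 0.07) and AKAP12 at -0.20 (SE 0.08). It passed without ACR_yes replicate 7, at -0.578 (adjusted p = 0.0181), and was at -0.437 with the component of the other 64 arrays as a covariate (adjusted p = 0.144). With the Neutrophil, T cell, Erythroid and Platelet scores as covariates it was -0.197 (adjusted p = 0.585). Camera with a preset correlation also called it, with an adjusted p of 0.784 with an estimated correlation. The Neutrophil list differed by -0.31 (adjusted p = 0.387). Of its 14 measured members 2 fell in limma over all rows tested, the decoy receptor TNFRSF10C by 0.79 (SE 0.20) and the keratin KRT23 by 0.74 (SE 0.21). Adjusted over the list alone 2 were lower and 1 was higher, the calcium-binding protein S100A8 at 0.28 (SE 0.09). Granule genes of immature neutrophils differed by 0.157 (adjusted p = 0.675), with the collagenase MMP8 at 1.45 (SE 0.56). Without 1 array this ran from 0.0188 to 0.232, and it was 0.559 in the lower title number range and -0.0232 in the higher. Differences were -0.245 for the Monocyte list (adjusted p = 0.457), -0.201 for the Dendritic cell list (adjusted p = 0.392) and -0.346 for the Erythroid list (adjusted p = 0.419). Without 1 array the Neutrophil list ran from -0.465 to -0.2, the Monocyte list from -0.36 to -0.137 and the Dendritic cell list from -0.358 to -0.109.

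Lymphocyte lists showed no difference that passed. The T cell list differed by 0.0551 (95% bootstrap interval -0.62 to 0.678, adjusted p = 0.865), the Naive and memory T cell list by 0.044 (adjusted p = 0.865) and the Regulatory T cell and checkpoint list by 0.0353 (adjusted p = 0.823). Their signs were not stable, since without 1 array they ran from -0.109 to 0.269, from -0.11 to 0.21 and from -0.0743 to 0.0977. The Cytotoxic lymphocyte list differed by -0.3 (adjusted p = 0.387), with the cathepsin CTSW at -0.56 (SE 0.19) and the chemokine CCL5 at -0.59 (SE 0.24). The differences were -0.0893 for NK cells (adjusted p = 0.675), -0.224 for B cells (adjusted p = 0.576) and -0.192 for plasma cells (adjusted p = 0.387), with ranges of -0.168 to -0.0433, -0.337 to -0.112 and -0.257 to -0.117 without 1 array. T cell costimulation and cytokine signalling differed by -0.185 (adjusted p = 0.419), and by -0.0684 without ACR_yes replicate 7. In the lower title number range it was 0.0528 and in the higher -0.312. Of its 18 measured members 2 fell in limma, both over all rows tested and when adjusted over the list alone, the kinase JAK1 by 0.58 (SE 0.13) and STAT3.

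Interferon genes did not separate the groups. The Interferon response list differed by 0.0894 (95% bootstrap interval -0.303 to 0.512, adjusted p = 0.823), with IFI44 at 1.06 (SE 0.43), and the Interferon gamma response list by 0.0786 (adjusted p = 0.759). The title number ranges went opposite ways, at -0.337 and -0.095 in the lower and 0.319 and 0.169 in the higher, and without 1 array the lists ran from -0.0547 to 0.17 and from -0.0949 to 0.138. Differences were -0.105 for MHC class I presentation (adjusted p = 0.675) and -0.292 for MHC class II presentation (adjusted p = 0.419), with ranges of -0.2 to 0.00686 and -0.398 to -0.183 without 1 array. The Inflammatory cytokine and NF-kB list differed by -0.329 (permutation p = 0.0326, adjusted p = 0.163), with IL1B, which encodes interleukin 1 beta, at -0.60 (SE 0.22). Immediate early genes, which drawn blood can also induce on handling, differed by -0.339 (adjusted p = 0.292), and by -0.645 without ACR_yes replicate 7 (adjusted p = 0.00375). With the first principal component of the other 64 arrays as a further covariate this became -0.179 (adjusted p = 0.266), and with all arrays and the 4 composition scores as covariates the sign turned, at 0.134 (adjusted p = 0.585). The Glucocorticoid response list differed by -0.203 (adjusted p = 0.535; -0.294 to -0.107 without 1 array), with 1 member lower when adjusted over the list alone, the kinase SGK1 at -0.53 (SE 0.15).

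Housekeeping lists gave positive differences in part. The Respiratory chain list differed by 0.336 (adjusted p = 0.292), with 1 of 13 measured members higher when adjusted over the list alone, the complex I subunit NDUFS4 at 0.77 (SE 0.24). Camera with a preset correlation called it, with an adjusted p of 0.784 with an estimated correlation. Ubiquitin and proteasome genes differed by 0.164 (adjusted p = 0.675), and adjusted over the list alone the proteasome subunits PSMA4 (1.06, SE 0.30) and PSMA2 (0.71, SE 0.25) were higher and PSMB3 (-0.47, SE 0.16) was lower. Without ACR_yes replicate 7 the Respiratory chain list passed at 0.509 and the proteasome list at 0.564 (adjusted p = 0.048 for both), and the Dendritic cell list passed at -0.358 (adjusted p = 0.048). With the component of the other 64 arrays as a covariate these became -0.0335 (adjusted p = 0.921), -0.0133 (adjusted p = 0.935) and -0.238 (adjusted p = 0.224). With all arrays and the 4 composition scores as covariates they were 0.0146, -0.258 and -0.043 (adjusted p = 0.939, 0.585 and 0.873). The Cytosolic ribosome list, with 7 of its 22 genes measured, differed by 0.157 (adjusted p = 0.675). Without 1 array this ran from -0.0263 to 0.409, the latter without ACR_yes replicate 7 (adjusted p = 0.283), and it was -0.332 with the component as well and -0.228 with the composition scores. Without the arrays over the quality limit 16 of the 30 lists moved by over 1.5 times, 1 of them changing sign, and with the composition scores 18 of 26 did, 7 of them changing sign. Further differences were -0.0876 for Unfolded protein and heat shock (adjusted p = 0.675) and -0.137 for Apoptosis (adjusted p = 0.538), which turned to 0.0428 and 0.0262 without ACR_yes replicate 7. Leaving out 1 array moved 22 of the 30 lists by over 1.5 times for at least 1 array, and 9 of these changed sign. Adjusted over the list alone 2 Apoptosis genes were lower, BCL2L11 at -0.38 (SE 0.12) and CFLAR. Of the 4 lists that camera called with a preset correlation, 0 held with an estimated correlation.

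**Figure D3:**
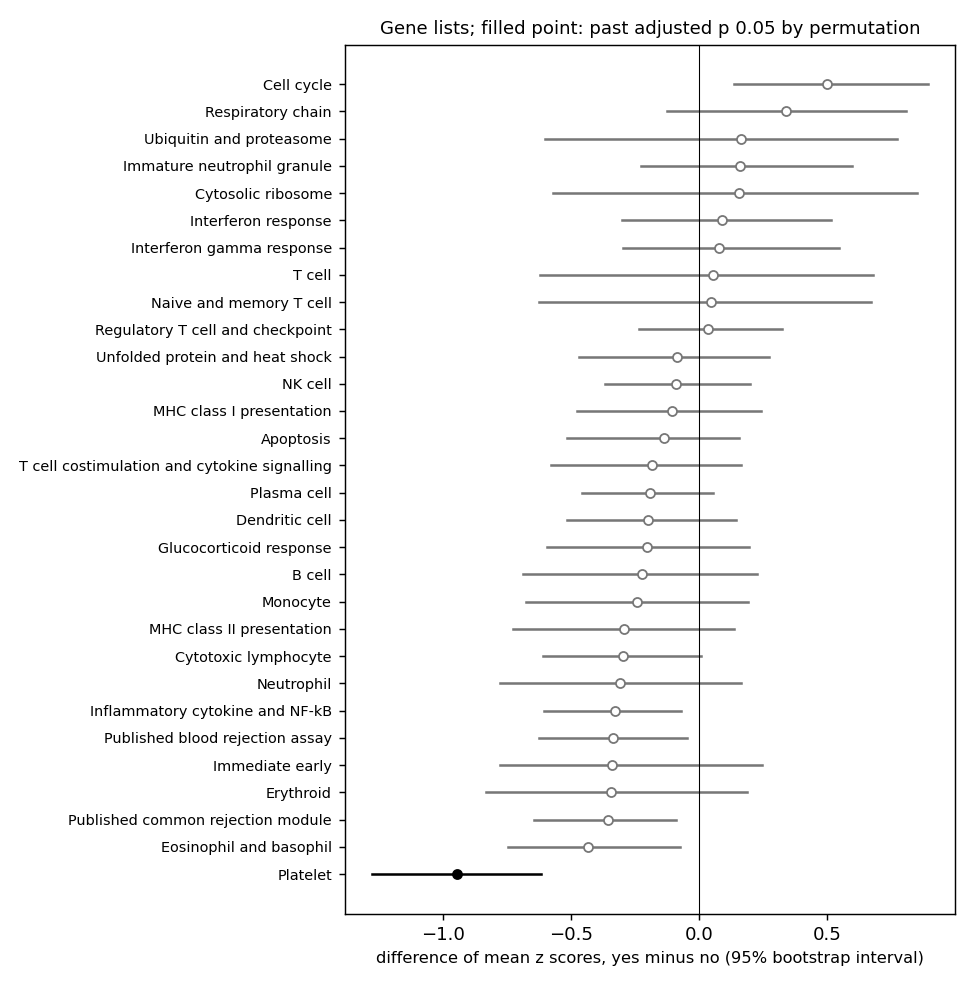
Differences of mean z scores, ACR yes (n = 12) minus ACR no (n = 53), for the 30 gene lists, with lines giving 95% bootstrap intervals. The Platelet list at -0.945 (filled) is the 1 list past an adjusted permutation p of 0.05, and the Cell cycle list at 0.497 lies at the other end.

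The series was deposited as a set for testing gene signatures, so a classifier was trained and tested within these arrays. In cross-validation its area under the ROC curve on held-out arrays was 0.74 (SD 0.0317 over 20 repeats, range 0.672 to 0.799). At 5 repeats it was 0.745, against a mean of 0.5 and a highest value of 0.851 in 100 permuted labellings (one-sided permutation p = 0.0495). Trained on the lower range of title numbers and tested on the higher, the area was 0.758 (8 ACR yes, 31 ACR no, one-sided exact rank test p = 0.0125). Trained on the higher range and tested on the lower, it was 0.795 (4 and 22, one-sided exact rank test p = 0.0344).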

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

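Leaving out each array in turn and the first principal component as a covariate were chosen after seeing the data. The 235 rows called became 381 with quantile normalisation on top, 1514 with array weights (49.9% lower), 586 at a threshold of 0.10 and 480 with the component, and 243 with the unlisted rows included, also added after seeing the data. Median centring, trend and robust settings of eBayes, the range as a block and 1 row per gene gave 196 to 275. They became 4 without the arrays over the quality limit, 3 within the higher title number range, 0 within the lower range and 0 with Neutrophil, T cell, Erythroid and Platelet scores as covariates (1762 rows at an unadjusted limma p of 0.05). In that last fit 232 of the 235 rows kept their sign, and the cause was not tested. The Platelet score among its covariates differs between the groups, so part of the loss of calls is built in. Dropping the lowest 25% of rows gave 205 calls, of which 83.9% were lower, and dropping the lower 50% gave 273, of which 85.7% were lower. Without 1 array the count ran from 10 to 2995. The 24 named genes were not followed through the fits without 1 array. In the other settings that held them they kept their sign, and they passed in each but the composition covariates (0), the quality limit (0), the lower range (0) and the higher range (2). The 1 list called became 2 without genes of the lower 50% by level, 4 by camera with a preset correlation, 0 by camera with an estimated correlation, 0 within the lower range, and 0 with composition scores as covariates, where the Platelet list itself was not tested. The setting without genes of the lower 50% by level tested 29 lists, as the Cell cycle list kept under 5 genes there. Without 1 array 1 to 8 lists passed. The Platelet difference stayed between -1.02 and -0.755 in z score settings adjusted over the lists and passed in each but the lower range, over fits that changed 1 choice, and was -0.723 with Neutrophil, T cell and Erythroid scores as covariates (permutation p = 0.00012, not adjusted). The classifier's area of 0.74 became 0.795 when trained on the higher range and ran from 0.696 to 0.809 without 1 ACR yes array. Dim rows near the floor of the arrays can understate a change, or differ for reasons other than expression. The rows called higher had a median level of 4.72 against 6.02 for all rows tested, and neither was excluded for them.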

Other observations

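Chosen after the result was seen were the lists of kinetochore, DNA replication and further platelet genes, the 3 explanations weighed for the Platelet list, and all fits without ACR_yes replicate 7 or with a component. Some genes of the kinetochore, the structure that attaches chromosomes to the spindle, were among the dim rows called higher in ACR yes. Named after their values were seen, NUF2 rose by 0.69 (SE 0.12, limma adjusted p = 0.00233), SGO2, a protector of centromere cohesion, by 0.47 (SE 0.09), the kinesin CENPE by 0.62 (SE 0.13) and CENPQ by 0.74 (SE 0.16). A hypothesis was that division genes rose beyond these. A list of 32 other kinetochore genes, of which 22 were measured, was higher by a mean z score of 0.473 (permutation p = 0.00031, adjusted over 3 lists 0.00093). These genes can vary together with those already seen in the same arrays, and the p does not allow for that choice of list. In the kinetochore list 19 members were above 0 and 3 below, and 9 of 12 ACR yes arrays lay above the ACR no median. CENPK differed by 0.94 (SE 0.31), KNL1 by 0.52 (SE 0.16) and CENPU by 0.34 (SE 0.10), and 0 of its members passed in limma over all rows tested. The score stayed past its threshold without any 1 array (adjusted p up to 0.00528) and without the arrays over the quality limit, at 0.506. DNA replication genes, 34 measured, were higher by 0.245 (adjusted p = 0.0266), with the polymerase subunit POLE2 at 0.35 (SE 0.10) and GINS4 at 0.36 (SE 0.13). In it 22 members were above 0 and 12 below, and 7 of 12 ACR yes arrays lay above the ACR no median. Without ACR_yes replicate 7 its difference was 0.279, and 0.0121 with the first principal component of the other arrays as a covariate (adjusted over 3 lists p = 0.903). This list passed in 61 of 65 fits without 1 array, and not without ACR_yes replicate 3 (adjusted p = 0.0576), replicate 4 (0.0542), replicate 5 (0.126) or replicate 11 (0.0556).

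A further list of 32 platelet genes that shares none with the Platelet list had 27 measured members, 26 of them below 0. Its score differed by -0.543 (adjusted over 3 lists p = 0.0099), and 11 of 12 ACR yes arrays lay below the ACR no median. PTGS1, the cyclooxygenase of platelets, fell by 0.50 (SE 0.14, limma adjusted p = 0.0401) and was the 1 member to pass in limma. The calmodulin-binding protein NRGN differed by -0.51 (SE 0.14), the inhibitory receptor MPIG6B by -0.45 (SE 0.13) and the adhesion protein THBS1 by -0.53 (SE 0.19). The member above 0 was GP5, at 0.05 (SE 0.06). Without any 1 array the list's adjusted p stayed at or below 0.0373. Without ACR_yes replicate 7 the list differed by -0.693, and by -0.176 with the first principal component of the other arrays as a covariate (adjusted over 3 lists permutation p = 0.407).

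The number of rows called could come from a structure of the samples. With all arrays 5 of 100 splits of the arrays into 12 and 53, the real one included, gave 235 or more rows, with 3241 as the highest other, so chance was not excluded, and a split with many times the real count points to such a structure. Without ACR_yes replicate 7, 2995 rows were called and 1 of 100 splits, the real one, gave as many (highest other 1261), but this array was chosen after its effect on the count was seen, a choice the other splits did not have, so chance was not excluded for that count either. The first principal component of the remaining 64 arrays held 26.9% of the variance and differed by -1.12 SD units (permutation p = 0.00044), and with it as a covariate 0% of the 2995 rows remained called and limma called 0 in all (1615 at an unadjusted p of 0.05, against 5665 without it). A broad axis that differs between the groups is thus a candidate explanation for the count, and whether it stands for blood composition, sample handling or the diagnosis was not tested. The count was 990 without ACR_yes replicates 7 and 9, and 26 without replicates 4, 7 and 9.

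For the lower Platelet list, outlying arrays were argued against, since it passed without the arrays over the quality limit (adjusted p = 0.0198). A smaller share of platelet RNA in the blood of ACR yes stays a candidate. The further platelet list also fell, by a mean z score of -0.543. Platelet genes of the same arrays can also fall together with a broad axis, so that list cannot tell these explanations apart. The fact that 100% of measured members were lower restates the fall of the Platelet list itself. With Neutrophil, T cell and Erythroid scores as covariates the difference was -0.723 (permutation p = 0.00012). The broad axis stays open as well: without ACR_yes replicate 7 the component took the difference from -1.02 (SE 0.224) to -0.485 (SE 0.189). The difference shrank and its spread did not grow. Its permutation p went from 6e-05 to 0.0114, and its adjusted p from 0.0018 to 0.114. The adjustment also depends on the p values of the other lists, so the shrinkage alone need not have ended the call. With all arrays and their own component the list passed at -0.755 (adjusted p = 0.0012). That component differed by -0.503 SD units between the groups (permutation p = 0.118), less than the component of the 64 arrays. As a covariate it could thus take away less of a group difference, so this pass does not weigh against the axis. The further platelet list fell to -0.176 with the component of the 64 arrays (adjusted p = 0.407).

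For the higher Cell cycle list, a lift of all dim rows was argued against, since random lists matched on level centred at -0.01, against its median log2 difference of 0.16. That value lay at percentile 99.98 of the random lists, whose 99th percentile was 0.08. Their genes were drawn singly, without the correlation among this list's genes (estimated at 0.33), so the percentile overstates how rare the value is. The broad axis was also argued against as the whole source of the list's rise: without ACR_yes replicate 7 the component left 106% of the difference, 0.556 before (SE 0.2) and 0.59 after (SE 0.222, permutation p = 0.00939). Its permutation p without the component was 0.00707, so the unadjusted p moved little. Over the 30 lists the adjusted p went from 0.0432 to 0.114 with the component. The adjustment also depends on the p values of the other lists, so the end of the call does not show a weaker difference of this list. Without replicate 7 and with the component the kinetochore list, at 0.575 before it, stayed past its threshold at 0.346 (adjusted over 3 lists p = 0.0146), but the DNA replication list, at 0.279 before it, was at 0.0121 (adjusted p = 0.903), so the axis stays open for that list. With all arrays and Neutrophil, T cell, Erythroid and Platelet scores as covariates the Cell cycle difference was 0.31 (permutation p = 0.114), so blood composition stays open, as does the hypothesis of a larger share of dividing cells in ACR yes, which no cell count here can test.

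Of 100 splits of the arrays, the real one included, 5 gave as many gene lists as the 1 called. The highest other count was 2. That count cannot decide on chance, because the threshold itself lets some random splits call a list. It also does not measure how strong a call is. The permutation test of the Platelet list, the 1 called, gave p = 4e-05 (adjusted over the 30 lists p = 0.0012). Log2 differences in the 2 ranges of title numbers correlated across rows with r = 0.542, where 1 of 100 labellings permuted within ranges was as high, at 0.558, and rows are not independent. 21 of the 30 lists had the same sign in both ranges.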
